A study of Homo sapiens with 6 samples.

How the data were processed

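RNA was measured by sequencing in 6 libraries of LNCaP, an established androgen-sensitive human prostate cancer cell line. Per the labels, 3 libraries came from cells carrying a hairpin against RB (shRB) and 3 from cells carrying a control hairpin (shCON). All cells spent 72 h in a treatment the labels call CDT and list as a cell cycle arrest treatment, and the series describes the condition as lacking hormone. Total RNA was extracted and made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. The labels do not say whether the replicates of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. They give 1 hairpin label per group, so an effect of RB loss and an effect of the particular hairpin or cell population were not separated by the design.

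The authors deposited raw read counts, 1 whole number per transcript ID and library, with no normalization. STAR, HOMER, edgeR and the genome build hg19 are named in the submitters' processing notes, without versions or the step each served. The column that names the rows is headed as transcript or repeat ID, per the file headers. The annotation, the counting options and the use of strand are not given in the sources used here, so antisense and overlapping genes and near-identical gene copies may share reads. The count table held 22279 Ensembl transcript IDs, of which 5693 were at 0 in every library. By ID, 22182 matched a transcript of GENCODE release 29, covering 22104 genes, and 76 genes had more than 1 ID. The 97 unmatched IDs held 0.38% of the counts and were kept in library totals. GENCODE release 29 describes another build than hg19 and was used only for gene names, chromosomes, gene order, exon overlap, transcript length and GC content, and no coordinates are given. Genes of the fixed lists without a row in the table were not analysed here.

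Total counts per library were 20091488, 9958278 and 6115310 for shCON 1 to 3 and 10898768, 9780579 and 10249720 for shRB 1 to 3. The 20 most abundant IDs held 6.76% to 7.46% of each total. Pairs of replicates differed by 2.26 to 11.3 times the sampling noise (chi-square per degree of freedom over genes), so no library was counted as a duplicate of another. Folds for genes at 0 use a floor of 3 counts over the group. The lower limits beside them are those of exact 95% binomial intervals and cover counting error only.

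The comparison of shRB with shCON was made with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr at its defaults (minimum count 10, minimum total 15), normalized by TMM and tested by the quasi-likelihood F test (glmQLFit, glmQLFTest) with group as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels are given as CPM, the count scaled to the TMM-adjusted library total. Before the data were examined, 23 gene lists were fixed, 8 of them primary. The primary lists held G1/S, DNA replication, G2 and mitosis, recombination repair, androgen-induced, androgen-repressed, neuroendocrine and p53-induced genes. The 15 secondary lists held S-phase chromatin, replication histone, pocket protein and CDK, MYC-regulated growth, interferon, amino acid and protein stress, sterol and fatty acid, respiratory chain, hypoxia and glycolysis, immediate early, luminal, basal, mesenchymal and stromal, leukocyte and ribosomal protein genes. Lists with at least 5 tested members (21 lists) were tested as sets with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation. The fry test, which asks whether members move on balance one way or change in either direction, was run beside it. Adjusted p-values of list tests are over the 21 lists.

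Named genes followed a rule fixed in advance. It took RB1, the 5 largest rises and 5 largest falls with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between groups, and the tested members with the smallest p in each list (3 per primary and 2 per secondary list). Symbols beginning LOC, LINC, MIR, SNOR or RNU, or holding -AS, were left out of the largest rises and falls. Some genes that the rule takes are not reported here. Genes named outside the rule are identified as chosen after their values were seen.

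The procedure was tested on simulated counts for the shRB and shCON comparison (11671 genes tested, 200 changed). It recovered 12% of genes changed 1.25-fold, 74% at 1.5-fold, 86% at 2-fold and 98% at 4-fold, and 4 of 139 calls were false (2.88%). Alternatives planned before the data were examined were DESeq2 (version 1.42.0), limma-voom, robust fitting, 3 other normalizations, 2 other filters, the replicate number as a block, each library left out in turn, the 20 most abundant genes left out, an adjusted p threshold of 0.01 and the other set tests. Alternatives chosen after seeing the data were thinning all libraries to the smallest total, removing a GC trend with and without the block, and leaving out chromosome 21.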

Results

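The data set comprised 6 RNA-seq libraries of LNCaP prostate cancer cells kept for 72 h without hormone, 3 from cells with RB knockdown (shRB) and 3 from cells with a control hairpin (shCON). Total counts ranged from 6115310 to 20091488 in shCON and from 9780579 to 10898768 in shRB. The comparison asks which transcripts change when RB, the retinoblastoma tumour suppressor that restrains E2F transcription factors, is depleted in hormone-deficient conditions.

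RB1 mRNA (ENST00000267163, chromosome 13) was 54.7 ± 1.93 CPM in shCON and 5.02 ± 1.06 CPM in shRB (SD, n = 3 each), so that 9.18% of the control level was left. The 3 shCON libraries read 56.6, 52.7 and 54.7 CPM and the 3 shRB libraries 5.83, 3.82 and 5.41 CPM. The log2 fold change was −3.43 ± 0.13 (SE; edgeR, Benjamini-Hochberg adjusted p = 2.4e-09), and each library matched its label.

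Of 11712 genes tested, 1499 were higher and 1459 lower in shRB by edgeR at an adjusted p under 0.05. Among these, 157 were at least 2-fold higher and 285 at least 2-fold lower. The 5 largest rises under the naming rule were in PLEKHG6 (2.28 ± 0.41 to 17.2 ± 1.80 CPM), TOX3, an HMG-box protein (7.51 ± 1.26 to 53.5 ± 6.78), CWH43 (1.72 ± 0.19 to 10.8 ± 1.64), the cancer-testis antigen gene MAGEA4 (24.0 ± 3.09 to 143.8 ± 13.8) and the docking protein gene DOK6 (4.96 ± 1.71 to 26.2 ± 2.69; SD, n = 3 for all). Their log2 fold changes were 2.99, 2.79, 2.62, 2.56 and 2.40, with SE of 0.11 to 0.19 and edgeR adjusted p of at most 1.1e-06. MAGEA4 has close paralogs with which it may share reads, so its value is uncertain.

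The 5 largest falls under the rule reached or approached 0. HENMT1 (ENST00000402983), which encodes a methyltransferase of piwi-interacting RNAs, had 544 counts over the shCON libraries and 0 over the shRB libraries. That is 155-fold lower at a floor of 3 counts over the group, with an exact 95% lower limit of 125.7-fold. SOHLH2 (ENST00000379881), a germ-cell transcription factor gene, went from 453 counts to 0, 129-fold lower at that floor, with an exact 95% lower limit of 104.6-fold. EFS (ENST00000216733), an adaptor protein gene, fell from 26.6 ± 1.35 to 0.16 ± 0.15 CPM (957 against 5 counts). ECHDC1, which encodes a metabolite-proofreading decarboxylase, went from 10.4 ± 0.41 to 0.33 ± 0.29 CPM, and the neural adhesion gene CNTN5 from 35.8 ± 4.61 to 1.65 ± 0.65 CPM (SD, n = 3 for all; edgeR adjusted p of at most 2.8e-07 for the 5 genes). The nearest 2 tested genes on each side of CNTN5 had a median log2 fold change of −0.67. Fewer genes passed without shCON 1 (863 higher and 912 lower) and without shCON 3 (969 and 964). The library shRB 2 stood apart from shRB 1 and shRB 3 on the second principal component (15.8% of variance, −21.8 against 11.99 and 12.4), and its deviation from the group mean had a Spearman correlation of 0.69 with transcript GC content. The same correlation was −0.51, 0.52 and −0.09 in shCON 1 to 3, −0.50 in shRB 1 and −0.54 in shRB 3 (across 11674 genes, which are not independent replicates). With transcript length the correlation was 0.18, −0.10 and −0.06 in shCON 1 to 3 and 0.09, −0.32 and 0.39 in shRB 1 to 3. The log2 fold change itself had correlations of 0.15 with GC content, −0.11 with length and 0.13 with mean expression.

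**Figure D1:**
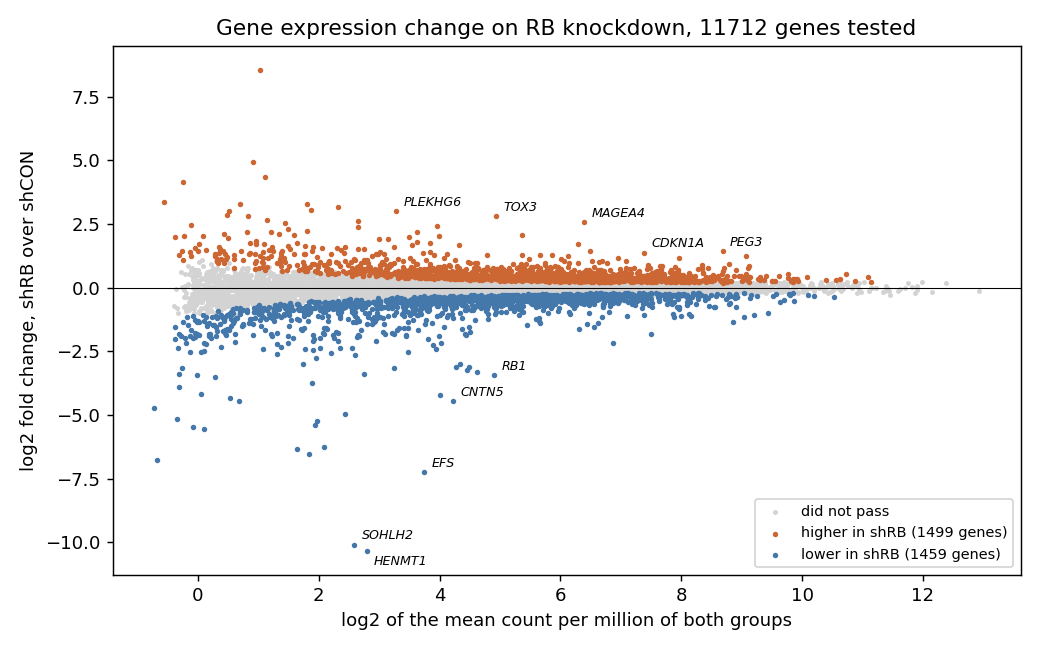
Log2 fold change of shRB over shCON (vertical axis) against the log2 of the mean CPM of both groups (horizontal axis) for the 11712 genes tested, with 1499 genes higher in orange, 1459 lower in blue and the others in grey. The plotted fold changes of HENMT1 and SOHLH2, at 0 counts in shRB, depend on the prior count of the fit and are not measured folds.

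Many cell cycle genes were higher in shRB, and none of the tested members of 4 lists passed as lower. In the G1/S list, 16 of 19 tested members rose, 0 fell and 3 did not pass (median log2 fold change 0.52). CDC25A, the phosphatase that activates cyclin-dependent kinases, rose from 14.8 ± 0.40 to 29.3 ± 2.37 CPM, thymidine kinase TK1 from 172.1 ± 11.998 to 303.9 ± 36.7, and the sliding clamp PCNA from 158.8 ± 11.3 to 247.7 ± 16.4 (SD, n = 3; edgeR adjusted p of at most 7.2e-05). E2F1 and the cyclin gene CCNE1, both chosen after their values were seen, rose by 0.52 and 0.57 on the log2 scale. In the DNA replication list, 20 of 27 rose, 0 fell and 7 did not pass (median 0.48). The helicase subunits MCM2 (124.6 ± 0.66 to 224.6 ± 15.5 CPM) and MCM4 (108.4 ± 0.58 to 163.2 ± 5.17) and the flap endonuclease FEN1 (74.9 ± 4.56 to 122.2 ± 9.42) had the smallest p.

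In the G2 and mitosis list, 25 of 29 members rose, 0 fell and 4 did not pass (median 0.55), among them the mitotic kinase PLK1 (68.5 ± 2.97 to 119.9 ± 8.24 CPM), the spindle factor TPX2 (86.1 ± 0.39 to 138.9 ± 6.87) and CDK1 (144.7 ± 13.2 to 258.3 ± 27.3; SD, n = 3). In the recombination repair list, 10 of 22 rose, 0 fell and 12 did not pass (median 0.44). The exonuclease EXO1 rose from 7.64 ± 0.73 to 16.1 ± 2.19 CPM, RMI2 of the BLM helicase complex from 14.7 ± 1.77 to 25.02 ± 1.09 and FANCI of the Fanconi pathway from 57.4 ± 1.90 to 87.6 ± 0.71. BRCA1 and BRCA2, chosen after their values were seen, were 0.42 ± 0.19 and 0.33 ± 0.28 on the log2 scale (SE) and did not pass. Without shRB 2 they were 0.65 and 0.66 and passed.

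As sets, the 4 lists were higher than other genes by limma camera, with adjusted p of 8.1e-09 (G1/S), 1.3e-11 (replication), 9.0e-13 (mitosis) and 1.7e-06 (repair). With an estimated correlation the camera adjusted p = 0.028 for replication and adjusted p = 0.045 for mitosis still passed, whereas adjusted p = 0.059 for G1/S and adjusted p = 0.059 for repair did not. Adjusted over the list alone, 16, 23, 25 and 12 members rose, in the same order, and 0 fell in each. Without shRB 2, 17, 25, 28 and 15 rose over all genes. In the repair list 13 members rose and 1 fell without a filter, and 14 rose and 1 fell with the replicate number as a block. CDC25A and MCM2 lie on chromosome 3, whose 663 tested genes had a median of 0.15, EXO1 lies on the part of chromosome 1 after its widest gap between tested genes, whose 499 tested genes had a median of 0.16, and the exons of FANCI overlap those of POLG on the opposite strand, which leaves the FANCI count uncertain.

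**Figure D2:**
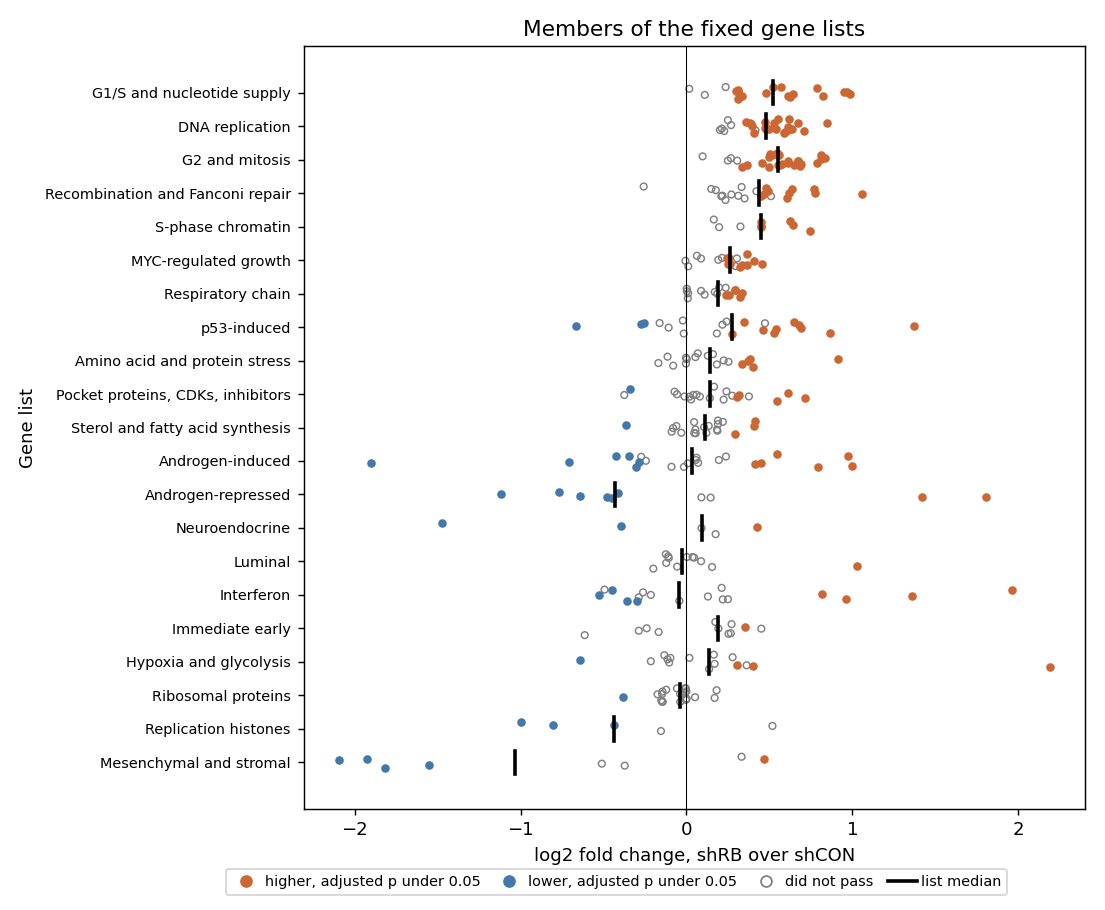
Log2 fold change of shRB over shCON (horizontal axis) of every tested member of the 21 gene lists tested as sets (vertical axis), with bars at the list medians. Filled points passed an adjusted p of 0.05 in edgeR (orange higher, blue lower), and the G1/S, replication, mitosis and repair lists hold no blue point.

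In the S-phase chromatin list, 6 of 9 members rose, 0 fell and 3 did not pass (median 0.45), including the histone chaperones CHAF1A (33.9 ± 1.49 to 52.97 ± 1.02 CPM) and ASF1B (31.0 ± 1.94 to 51.8 ± 7.44; SD, n = 3). In the S-phase chromatin set the camera adjusted p was 0.00027, and adjusted p = 0.059 with an estimated correlation. Of 5 tested replication histone genes, 0 rose, 3 fell and 2 did not pass (median −0.44). The other members in the table, HIST1H1A, HIST1H1B, HIST1H1D and HIST1H1E, had at most 8 counts in any library. The tested genes may therefore not stand for replication histones in general. HIST1H2BD fell from 26.9 ± 0.72 to 13.5 ± 0.37 CPM and HIST2H2BE from 206.9 ± 7.75 to 152.8 ± 1.32 (edgeR adjusted p of 1.8e-05 and 0.00049), with reads possibly shared among near-identical histone copies. In the list of pocket proteins, cyclin-dependent kinases and their inhibitors, 5 of 21 rose, 1 fell and 15 did not pass (median 0.14). CDK2 rose from 41.9 ± 2.58 to 68.3 ± 4.10 CPM and the inhibitor CDKN2C from 25.6 ± 0.33 to 37.4 ± 3.84, and the fall was in the inhibitor CDKN1B (140.3 ± 8.22 to 110.7 ± 7.28), chosen after its values were seen. The camera adjusted p was 0.029 for histones and 0.041 for the pocket protein list, and neither passed with an estimated correlation (adjusted p = 0.18 and adjusted p = 0.14). Adjusted over the list alone, the counts of higher and lower members were unchanged for these 3 lists. Without shCON 1 or without shCON 3, 3 members of the pocket protein list rose, its median ranged from 0.056 to 0.18 with 1 library left out, and HIST2H2BE lies on the same part of chromosome 1 as EXO1.

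Genes of androgen signalling moved in both directions. Of 22 tested androgen-induced genes, 6 rose, 6 fell and 10 did not pass (median 0.03). The prostein gene SLC45A3 rose from 66.7 ± 7.82 to 133.0 ± 7.49 CPM and the lipid phosphatase PLPP1 from 236.9 ± 3.79 to 410.0 ± 14.6, while the transcription factor MAF fell from 17.1 ± 0.78 to 4.57 ± 0.57 (SD, n = 3; edgeR adjusted p of at most 5.2e-06). Among genes chosen after their values were seen, the kallikreins KLK2 and KLK3 (prostate-specific antigen) rose by 0.98 and 0.45 on the log2 scale and FKBP5 by 0.55. Of 10 tested androgen-repressed genes, 2 rose, 6 fell and 2 did not pass (median −0.43, mean −0.04). The imprinted gene PEG3 rose from 223.9 ± 2.54 to 599.2 ± 62.2 CPM and the glucuronosyltransferase UGT2B11 from 5.58 ± 1.19 to 18.97 ± 2.87, whereas UGT2B17, which inactivates androgens, fell from 348.1 ± 22.9 to 160.1 ± 12.8.

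Neither androgen list stood apart from other genes by limma camera (adjusted p = 0.77 and adjusted p = 0.34). The fry test for change in either direction gave an adjusted p of 1.6e-05 for the induced and 8.2e-06 for the repressed list. This outcome was not particular to androgen genes. By this fry test every list passed except the ribosomal proteins (adjusted p = 0.25), including the luminal list (adjusted p = 2.8e-05). Adjusted over the list alone, 7 induced genes rose and 8 fell, and the repressed counts were the same. Reads may be shared between KLK2 and KLK3, among UGT2B genes, between PEG3 and ZIM2, and between PLPP1 and the opposite-strand gene MTREX, so these values are uncertain. SLC45A3 lies on the same part of chromosome 1 as EXO1, and PEG3 lies near the end of chromosome 19, where 40 neighbouring tested genes from ZNF582 on had a median of −0.40 (the lowest of 83 overlapping windows of that chromosome).

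Most neuroendocrine markers were at or near 0 in both groups. Of 22 markers in the table, 5 had enough counts to be tested, of which 1 rose, 2 fell and 2 did not pass. The neurotensin gene NTS fell from 64.3 ± 8.94 to 23.1 ± 4.18 CPM and neuronal enolase ENO2 from 84.6 ± 1.12 to 64.4 ± 6.99, while SYT4, a synaptotagmin, rose from 1865 ± 113.0 to 2501 ± 291.3 (SD, n = 3; edgeR adjusted p of at most 0.0054). The list did not pass as a set (limma camera adjusted p = 0.77; median 0.09, mean −0.24, test direction down), and adjusted over the list alone the counts were the same. Its median ranged from −0.05 to 0.14 with 1 library left out.

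In the p53-induced list, 10 of 21 members rose, 3 fell and 8 did not pass (median 0.28), with the same counts adjusted over the list alone. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 93.4 ± 2.78 to 242.0 ± 11.4 CPM, the secreted factor GDF15 from 174.0 ± 8.14 to 278.3 ± 4.02 and the exonuclease AEN from 42.5 ± 1.19 to 77.4 ± 8.84 (SD, n = 3; edgeR adjusted p of at most 2.6e-05). The set passed limma camera (adjusted p = 0.0043) but not with an estimated correlation (adjusted p = 0.075). Without shCON 1 and without shCON 3, 7 and 8 members rose and 1 fell in each.

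**Figure D3:**
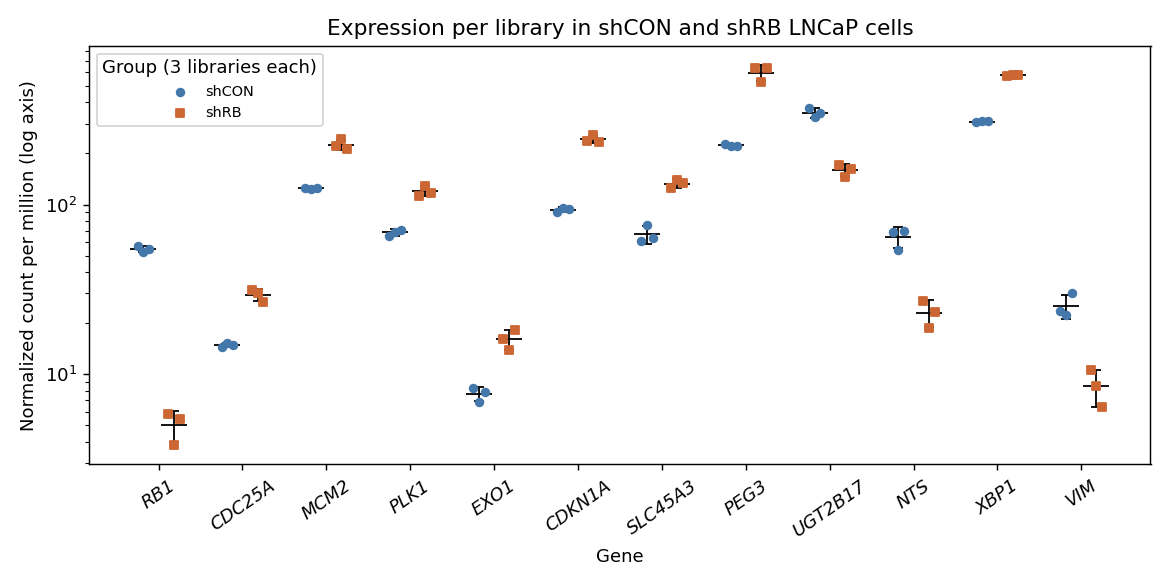
Normalized read count in CPM (vertical axis, logarithmic) of 12 genes in each of the 3 shCON libraries (blue circles) and 3 shRB libraries (orange squares), with the mean and SD in black. The 2 groups do not overlap for any gene shown, and RB1 lies at 52.7 to 56.6 CPM in shCON and at 3.82 to 5.83 CPM in shRB.

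In the list of MYC-regulated growth genes, mostly of ribosome biogenesis, 10 of 18 rose, 0 fell and 8 did not pass (median 0.26), led by the ribosomal RNA processing factor RRP9 (48.3 ± 3.57 to 66.3 ± 3.91 CPM) and the spermidine synthase SRM (219.5 ± 10.3 to 290.7 ± 30.1). Of those that rose, SRM and ODC1 act in polyamine synthesis, and HSPD1 and HSPE1 encode mitochondrial chaperones (ODC1, HSPD1 and HSPE1 chosen after their values were seen, at 0.27, 0.25 and 0.32 on the log2 scale). The exons of HSPD1 and HSPE1 overlap on opposite strands, so both counts are uncertain. HSPD1 lost its call in several alternative fits, and ODC1 lost its call without shCON 1 or without shCON 3. Fewer of the list rose without shCON 3 (4), without shCON 1 (6) and without shRB 3 (6). In the respiratory chain list, 6 of 16 rose, 0 fell and 10 did not pass (median 0.19), led by UQCRC1 (371.6 ± 16.2 to 469.1 ± 47.1) and CYC1 (253.0 ± 14.4 to 316.1 ± 28.7), both of complex III. The count was 1 without shCON 1, 2 without shCON 3 and 3 without shCON 2. In the amino acid and protein stress list, 5 of 18 rose, 0 fell and 13 did not pass (median 0.14). XBP1, a transcription factor of the unfolded protein response, rose from 308.2 ± 3.15 to 579.7 ± 5.06 CPM and DDIT4 from 197.4 ± 4.52 to 260.9 ± 4.77 (SD, n = 3). The camera adjusted p was 0.00031, 0.0087 and 0.014 for these lists and did not pass with an estimated correlation (adjusted p = 0.059, adjusted p = 0.33 and adjusted p = 0.11). Adjusted over the list alone, 13, 6 and 5 members rose and 0 fell. UQCRC1 and CYC1 no longer passed without shCON 1, RRP9 and UQCRC1 lie on chromosome 3, and XBP1 lies on chromosome 22, whose 313 tested genes had a median of 0.085.

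The sterol and fatty acid list had 3 of 20 members higher, 1 lower and 16 that did not pass (median 0.11; camera adjusted p = 0.085). The regulator SREBF2, on chromosome 22, rose from 292.5 ± 15.1 to 388.3 ± 25.6 CPM. In the hypoxia and glycolysis list, 3 of 15 rose, 1 fell and 11 did not pass (median 0.14; camera adjusted p = 0.33). Its median ranged from 0.057 to 0.17 with 1 library left out. Adrenomedullin ADM rose from 0.78 ± 0.12 to 3.82 ± 0.96 CPM and the collagen prolyl hydroxylase subunit P4HA1 fell from 114.3 ± 9.04 to 73.3 ± 2.03. The interferon list had 4 of 17 members higher, 4 lower and 9 that did not pass (median −0.04, mean 0.18, test direction up; camera adjusted p = 0.60). Its median ranged from −0.15 to −0.018 with 1 library left out, and over all alternatives from −0.22 without a filter to 0.039 without chromosome 21. The lower count was 0 without shCON 3, 1 without shRB 3, and 2 without shCON 1, shCON 2 or shRB 1. OASL rose from 2.88 ± 0.52 to 7.76 ± 1.44 CPM and RSAD2 from 0.56 ± 0.06 to 2.27 ± 0.38 (SD, n = 3 for all). Of 11 immediate early genes, 1 rose, 0 fell and 10 did not pass (median 0.19; camera adjusted p = 0.44). Their median ranged from 0.12 to 0.25 with 1 library left out, and was −0.19 under DESeq2 and −0.17 without a filter. The rise was in JUN (103.8 ± 6.58 to 132.8 ± 5.92 CPM), and ATF3 was 27.9 ± 2.22 and 33.4 ± 1.03 CPM (edgeR adjusted p = 0.074). Adjusted over the list alone, 2 sterol genes rose and 1 fell, and the counts of the other 3 lists were the same. Without shRB 2, 6 sterol genes and 2 immediate early genes rose and 2 hypoxia and glycolysis genes fell. ATF3 lies on the same part of chromosome 1 as EXO1.

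Most basal and leukocyte markers had too few counts to be tested. Of 12 luminal markers, 1 rose, 0 fell and 11 did not pass (median −0.03, −0.06 to −0.02 with 1 library left out, mean 0.05, test direction up; camera adjusted p = 0.87). The epithelial transcription factor ELF3 rose from 44.0 ± 3.34 to 89.0 ± 4.12 CPM, and HOXB13, a prostate lineage factor, was 1043 ± 51.0 and 908.1 ± 57.4 (edgeR adjusted p = 0.069). Without shRB 2, 4 luminal markers fell, and ELF3 lies on the same part of chromosome 1 as EXO1. Of 8 mesenchymal and stromal markers, 1 rose, 4 fell and 3 did not pass (median −1.03, −0.55 under DESeq2 and −0.51 without a filter). Vimentin VIM fell from 25.3 ± 4.15 to 8.48 ± 2.09 CPM, VWF from 9.76 ± 1.39 to 2.65 ± 1.00 and TWIST1, chosen after its values were seen, from 6.06 ± 0.31 to 1.40 ± 0.66 (SD, n = 3). The rise was in FN1, by 0.47 on the log2 scale (edgeR adjusted p = 0.0011). FN1 was chosen after its values were seen and was not followed through the alternative fits. The list's other markers in the table had at most 9 counts in any library and were not tested. The mesenchymal and stromal set passed limma camera (adjusted p = 0.011) but not with an estimated correlation (adjusted p = 0.13). Of 2 basal markers tested, ITGA6 fell from 32.6 ± 4.25 to 24.0 ± 1.60 CPM, a call lost without shCON 1, and ITGB4 was 14.4 ± 1.60 and 15.6 ± 1.30 (edgeR adjusted p = 0.44). The 1 leukocyte marker tested, CD68, was 5.92 ± 0.91 and 5.08 ± 0.15 CPM (edgeR adjusted p = 0.25). Adjusted over the list alone, 5 mesenchymal markers fell and 1 rose, and the luminal counts were the same.

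Ribosomal protein genes showed 0 of 21 members higher, 1 lower and 20 that did not pass (median −0.04; camera adjusted p = 0.36), with the same counts adjusted over the list alone. RPL32, on chromosome 3, was 1447 ± 66.1 and 1627 ± 125.4 CPM (SD, n = 3; edgeR adjusted p = 0.13). Reads may be shared with its processed pseudogenes. Without shRB 2 the list passed as lower, with a median of −0.11 and 7 members called, and the median ranged from −0.11 to 0.030 with 1 library left out. Over all tested genes, the CPM ranges of the 2 groups did not overlap for 41.1%, against 10% by chance.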

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

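The fits that thinned the libraries, removed a GC trend or left out chromosome 21 were chosen after the results were seen, and the others were planned. RB1 fell in all of these fits, with log2 fold changes of −3.56 to −3.27. The medians of the androgen-induced list (−0.01 to 0.06) and the neuroendocrine list (−0.39 to 0.19), which did not pass, changed sign in some fits, and those of the other 6 primary lists did not. Among secondary lists the interferon, immediate early and ribosomal protein medians changed sign in some fits. With an estimated correlation the G1/S, repair and p53-induced lists no longer passed, at unchanged medians of 0.52, 0.44 and 0.28, since that setting changes only the test. Counts of genes stayed within 1.5 times the reported counts under DESeq2 (1273 higher, 1127 lower), limma-voom, the other normalizations and filters, thinning (1244 and 1158) and without chromosome 21 (1468 and 1402). Leaving out 1 library gave 863 to 2074 higher and 912 to 1956 lower genes, with the lowest counts without shCON 1, counts of 969 and 964 without shCON 3, and the highest without shRB 2. An adjusted p threshold of 0.01 left 787 higher and 793 lower. With the replicate number as a block, 2203 genes were higher and 2294 lower. Same-numbered libraries had correlated deviations of 0.24, 0.35 and −0.0003, and 3 of 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples. Shared handling by number is not excluded. The correlation with GC content was alike in shCON 1 and shRB 1 (−0.51 and −0.50) and in shCON 2 and shRB 2 (0.52 and 0.69). It differed between shCON 3 and shRB 3 (−0.09 and −0.54). Removing the GC trend gave 2314 higher and 2255 lower genes, and with the replicate block 2475 and 2411. The cause was not tested for the block or the GC correction, and in simulated data (11705 genes) the GC fit made 14 false calls among 155 (9.03%), against 1.6% without that correction. Of 80 named genes other than RB1, 69 had the same outcome, a pass or none, in every alternative and 0 reversed. UQCRC1, CYC1 and ITGA6 lost their call without shCON 1, ODC1 without shCON 1 or shCON 3, and HSPD1 in several fits, while HOXB13, ATF3, RPL32, COL4A3BP, BRCA1 and BRCA2 passed in at least 1 alternative. Among secondary lists, 17 results lost and 5 gained a call. The pocket protein and replication histone lists lost theirs in several fits, the sterol list gained a call in some, and the ribosomal protein list gained one without shRB 2. In the simulation, 12% of the smallest changes were recovered (11671 genes), so changes of that size may be missed. The simulation changed 200 genes, whereas 2958 of 11712 genes passed in the data. Adjusted p-values depend on how many genes change, so the simulated recovery does not give the share missed in these data.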

Other observations

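The tests of the share of cycling cells, of fewer copies of chromosome 21 and of depth for the nearly silent genes, with the scan of gene families and the look at neighbours of single genes and at parts of chromosomes 1 and 19, were chosen only after the result each measures was seen. Of 17 tested genes with symbols beginning COL, 9 fell, 1 rose and the others did not pass, among them COL4A3BP, which encodes a ceramide transporter and no collagen (median log2 fold change −0.51; limma camera adjusted p = 0.00019 over 194 families, adjusted p = 0.97 with an estimated correlation). COL12A1, a fibril-associated collagen, fell from 25.9 ± 4.62 to 4.95 ± 0.21 CPM and COL6A1, a microfibrillar collagen on chromosome 21, from 281.6 ± 10.8 to 79.9 ± 11.2 (SD, n = 3 each). Both genes were chosen after their values were seen, and 3 of the 9 that fell lie on chromosome 21.

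Other families moved as blocks. All 12 tested protocadherin genes of the PCDHGA group rose, by 0.36 to 0.43 on the log2 scale, and all 9 tested UGT1A genes, which encode bilirubin and drug glucuronosyltransferases, by 0.95 to 1.22 (edgeR). Members of each group share their last exons, and the smallest total count in a group was 67.2% and 89.1% of the largest, so each group counts as 1 signal rather than as independent genes. VNN1, which encodes pantetheinase and was chosen after its values were seen, had 0 counts over the shCON libraries and 127 over the shRB libraries (4.09 ± 0.88 CPM; SD, n = 3).

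In all, 2958 genes passed in either direction by edgeR, and 442 of these by at least 2-fold, against at most 0 and 0 under the other splits of the 6 samples into 3 and 3. The set test called 12 lists under the real grouping and at most 8 under another. Of the 10 splits, 1 gave a result as large in each of the 3 cases, the real one. With 10 splits the share cannot lie under 0.05, and no more can be said from them.

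There were 19 genes whose transcripts were nearly silent in shRB (log2 fold change of −4 or less), HENMT1, SOHLH2 and EFS among them, against 4 changed as much in the other direction. With every library thinned to the smallest total, the summed shRB count lay a median of −5.22 from the summed shCON count on the log2 scale. It lay at −3.97 or below for every gene. The genes had been selected on a fold change already normalized for library totals, so thinning could hardly give another outcome and does not test depth. The nearest 2 tested genes on each side had a median of −0.078, which argues against loss of a segment that spans the neighbours for the set as a whole. It was not tested gene by gene and stays open for single genes: neighbours of CNTN5 and GAS1 had medians of −0.67 and −0.55. LACC1 and CCDC122 of the set are adjacent on chromosome 13, so each is a neighbour of the other, and had neighbour medians of −0.59 and −0.63. SOHLH2 lies on chromosome 13 too, as does RB1, and its neighbour median was 0.16. GAS1, LACC1 and CCDC122 were chosen after their values were seen. Candidate explanations that stay open, untested, are RB loss itself, promoter silencing, small deletions, an unintended target of the hairpin, and a different founding population of the shRB cells.

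Chromosome 21 was lower as a whole in shRB. Of its 123 tested genes, 78 fell and 0 rose by edgeR (94.3% had a negative log2 fold change), the median was −0.38 (0.769-fold), and the chromosome passed limma camera among 23 chromosomes (adjusted p = 1.0e-18, adjusted p = 0.0038 with an estimated correlation). Its genes lay a median of −0.380 from genes of other chromosomes matched on length, GC content and expression, which argues against those biases, and the 3 shRB libraries lay at −0.382, −0.368 and −0.381, which argues against 1 divergent library. The medians of its first, middle and last parts by gene order were −0.430, −0.402 and −0.375. Fewer copies in the shRB cells stay open and are not shown, since the data that raised this explanation cannot also support it (3 in place of 4 would give −0.415). Whether such a loss came with RB depletion or was present in the cells that founded the shRB line was not tested, and replicates of 1 line would share it.

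By limma camera with the preset correlation, chromosome 3 was higher (188 genes higher, 40 lower, median 0.15, adjusted p = 3.0e-05), as was chromosome 22 (76 higher, 22 lower, median 0.085, adjusted p = 0.0075). Neither passed with an estimated correlation (adjusted p = 0.24 and adjusted p = 0.90). On chromosome 1, the 499 tested genes after the widest gap had a median of 0.16 (154 higher, 29 lower) and the 677 before it −0.07 (56 higher, 101 lower), with no set test of the parts. In a scan of 1087 overlapping windows of 40 neighbouring tested genes, 39 lay below −0.18 and 75 above 0.16, limits that 0.1% of random gene sets pass on each side. The low windows lay on 10 chromosomes, with the lowest medians on 21 (all of its 9 windows were low), 19 (−0.40, from ZNF582 on, although PEG3 in it rose), 6 (−0.27), 11 (−0.24), X (−0.23), 2 and 15 (−0.22 each). The high windows lay on 7 chromosomes, with the highest medians on 5 (0.40), 3 (0.32), 1 (0.27), 22 (0.23) and 2 (0.21). On chromosome 5 only 3 of 50 windows were high, and its 531 tested genes had a median of −0.004. The limits treat genes as independent. A window holding a group with shared exons, such as PCDHGA or UGT1A, could pass them on 1 signal, and this was not checked.

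The 75 tested members of the G1/S, replication and mitosis lists had a median log2 fold change of 0.54. They exceeded genes matched on length, GC content and expression by 0.51 (the highest median of 1000 matched draws was 0.13). They exceeded their chromosome neighbours by 0.56. These excesses argue against biases of length, GC content or expression and against copy number. The members' median stayed at 0.54 with every library thinned to the smallest total. The fold changes were already normalized for library totals, so thinning could hardly give another outcome and does not test depth. A larger share of cycling cells stays open, as does a direct effect of RB loss on E2F target genes, as untested. The mitosis median lay 0.029 above the G1/S median, which supports neither, since both would raise genes of both phases and the medians had been seen.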
